A study of Drosophila melanogaster with 36 samples.

How the data were processed

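RNA was measured in heads and abdomens of adult Drosophila melanogaster females of a standard base population. The females were either virgins or had been mated at 3 days of age to males from 1 of 6 experimentally evolved populations. Of these populations, 3 had been kept under monogamy (M1, M2 and M3) and 3 under polygamy (P1, P2 and P3), for 182 generations followed by 1 generation in a common environment. Each population was held at a census size of 200, and polygamous groups consisted of 5 females and 5 males. All females were frozen at 4 days of age, 24 h after mating in the mated groups, and each sample pooled tissue of 20 females. Per the labels' protocols, libraries were made with a stranded total RNA kit after removal of ribosomal RNA.

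Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.33, aligned with TopHat2 2.1.0 to the BDGP6 assembly and counted per gene with HTSeq 0.6.1. The deposited table held whole-number counts of reads for 17552 genes, with no normalisation by the authors. The annotation release, the strand setting of the counting and the handling of ambiguous reads are not given in the sources used here. Counts of overlapping antisense RNAs and of near-identical gene copies are therefore uncertain. Some of the copies named in the text are marked as such, but other named genes with similar copies may not be. Every deposited column belonged to a named sample, and no line of the table lacked a gene. Gene symbols and coordinates came from Ensembl annotation release 115 of BDGP6, in which 17387 of the gene identifiers were found.

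The 36 deposited samples were 2 sequencing runs of each of 18 libraries. Counts of both runs of a library differed by 1.81 to 3.32 chi-square units per degree of freedom over genes with at least 20 counts. Libraries of a group differed by 29.9 to 177 on the same measure. The runs were therefore summed, and n counts libraries. The libraries formed 6 groups of 3: virgin, mated to monogamous males and mated to polygamous males, in each tissue. A mated library corresponds to 1 evolved population of males, so the unit of replication between regimes was the male population. Nothing in the labels says whether the virgin pools came from separate cultures, and p-values measure the spread between these pools.

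Totals ranged from 40396031 to 64761633 counts per library. With 3 counts as the floor for a group at 0, the 3 virgin abdomen libraries together allowed a level of at most 0.0194 counts-per-million (CPM), which covers counting error alone. The common biological coefficient of variation was 0.172 in abdomens and 0.272 in heads, with 6 residual degrees of freedom in each tissue.

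Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with TMM normalisation, the package's expression filter, robust dispersions and a prior count of 2 in fitted log2 changes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. Each tissue had 1 model with its 3 groups, and standard errors were the log2 change divided by the square root of the F statistic. The comparisons were mated (the mean of both male regimes) minus virgin, polygamous minus monogamous males (P minus M), and each regime minus virgin. A model over all 18 libraries tested whether the mating effect and the regime effect differed between tissues, expressed as abdomen minus head. A response score per library averaged, over genes called in the mated minus virgin comparison, the log2 CPM difference from the virgin mean, signed by the direction of the call. Scores of the regimes were compared by an exact 2-sided permutation test, for which 3 libraries against 3 give no p below 0.1.

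Gene lists, 37 in number with 1333 members in all, were written from general knowledge of fly biology, and 11 of their symbols were not found in the table. Lists with at least 3 tested members were tested on log2 CPM with camera of limma 3.58.1 at a preset correlation of 0.01, with p-values adjusted over the lists of a comparison. The same test with an estimated correlation and fry, which asks whether the members move one way without reference to other genes, were run beside it. Called members were also counted with p-values adjusted over the list alone. The lists described in full were chosen after the list results were seen.

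The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those named as later choices. The rule named the 8 largest rises and the 8 largest falls with an adjusted p below 0.05, a mean log2 CPM of at least 1 and no overlap between the groups. Where fewer than 5 genes passed, it named the 5 with the smallest unadjusted p, as genes that had not passed. It added up to 4 members per described list by smallest p, 5 genes each way for the differences between tissues, and 6 fixed genes of yolk and immunity. A few further genes, identified as such, were named after their values were seen.

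The tests were run first on simulated data with 200 genes changed by known folds, all drawn from genes with a mean log2 CPM of at least 1. In abdomens, 91.0% of genes changed 2-fold and 62.7% of genes changed 1.5-fold were called in a simulated mated minus virgin comparison over 10254 genes. In heads these shares were 92.5% and 49.3% over 10817 genes. For P minus M the shares were 83.6% and 38.8% in abdomens and 83.6% and 37.3% in heads. For the difference in mating effect between tissues they were 80.6% and 32.8% over 11544 genes. Of 20 simulated unchanged lists, 0 were called. Genes were simulated independently, so false calls that arise from correlation between the members of a list were not tested. All planted changes were present together, and smaller numbers of changed genes were not simulated, so the shares do not cover that case.

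The alternatives fixed in advance were thresholds of 0.1 and 0.01, a minimum change of 1.5-fold, DESeq2 1.42.0, limma voom, DESeq2 size factors, no filter beyond 1 count, a filter at a mean of 50 counts, dispersions without the robust step, each sequencing run alone, models with the compared groups alone, omission of the 10 most abundant genes, a block on the population number and omission of each library in turn. After the data had been seen, scaling on muscle and renal tubule genes, joint omission of head libraries virgin 1, M1 and M2, and the midgut protease level as a covariate were added. Remaining computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Genes below the expression filter were left out of the tests, some of the genes that the naming rule selected are not reported here, and reads, isoforms and sequence variants were not analysed here.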

Results

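The question posed by the design was whether the mating regime under which males had evolved altered the transcriptional response of the females they mated. Gene expression was profiled by RNA sequencing in heads and abdomens of females from a common base population. For each tissue there were 3 libraries of virgins, 3 of females mated to males of monogamous populations (M1 to M3) and 3 of females mated to males of polygamous populations (P1 to P3). Each library pooled 20 females frozen at 4 days of age, and mated females were taken 24 h after mating. Head libraries held 40396031 to 64761633 counts and abdomen libraries 41057456 to 56772245. Between 11881 and 13470 genes had at least 1 count in a library. Genes of ribosomal RNA, mitochondrial ones included, took 1.03% to 2.76% of counts. In abdomen virgin 1 their share was 1.91%, with the mitochondrial gene mt:lrRNA alone at 1.90%. The 10 most abundant genes took 17.4% to 21.9% in heads and 5.51% to 7.59% in abdomens. Levels are means ± SD in CPM over 3 virgin or 6 mated libraries, and log2 changes are given ± standard error. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

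In abdomens, mating was followed by higher expression of yolk, eggshell, antimicrobial, midgut protease and muscle genes and by lower expression of germline genes. Fcp3C, a follicle cell protein gene (FBgn0000644, X:3173376-3174474, BDGP6), rose from 1.33 ± 0.844 CPM in virgins to 59.5 ± 18.5 in mated females, a log2 change of 5.46 ± 0.58. The yolk protein gene Yp1 (FBgn0004045, X:10053811-10055498) rose from 2442 ± 357 to 7657 ± 1889 CPM. Tobi, an alpha-glucosidase gene (FBgn0261575, 3R:25344761-25346921), dropped from 85.9 ± 13.8 to 19.99 ± 6.48 CPM, a log2 change of -2.11 ± 0.26. In all, 5608 of 10350 genes (54.2%) differed, 2999 higher and 2609 lower in mated females, where 6318 genes had an unadjusted p below 0.05 against 517.5 expected by chance. Changes of at least 2-fold were mostly increases, with 1251 genes higher and 30 lower. The groups did not overlap for 5198 genes (50.2%), 4900 of them called, where chance gives 2.38% with 6 libraries against 3.

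The balance of rising and falling genes depended on the scale. When libraries were scaled on muscle and renal tubule genes, a choice made after the data were seen, the median of all genes moved to -0.90, and 473 genes were higher and 6943 lower. Each list median printed below that changes sign under this scaling is given with its value there, where the median of all genes serves as the reference. For mated minus virgin, a median printed without such a value kept its sign but was also shifted down, so its size depends on the scale. The muscle list helped to set the scale, so its own rise was not tested by it.

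Besides Fcp3C, the 8 largest rises included 2 immune genes and a pair of heat shock gene copies. Osi19 (FBgn0037429, 3R:6335362-6337196), a member of the Osiris gene family, had no count in any virgin library and 3.27 ± 3.66 CPM in mated females. Against a floor of 3 counts over the virgin group this was at least 169-fold higher (adjusted p = 0.0141), or 93.6-fold without P2, which held 10.5 CPM against 0.522 to 2.93 in the other mated libraries. Listericin (FBgn0033593, 2R:11241745-11242194), an antibacterial protein gene, rose from 0.924 ± 0.00845 to 24.7 ± 7.14 CPM, by 4.71 ± 0.21 (adjusted p = 4.0e-06). The attacin gene AttB (FBgn0041581) rose by 5.07 ± 0.66, although its counts are uncertain because AttA is nearly identical. CG14187 and CG14191 rose by 5.26 ± 0.38 and 4.72 ± 0.53. The near-identical copies Hsp70Bbb and Hsp70Bb had changes of 5.69 ± 1.51 and 4.72 ± 1.08, with uncertain assignment of reads between them. The call for Hsp70Bbb was lost without virgin 2 (adjusted p = 0.0515) or virgin 3 (adjusted p = 0.0601).

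Of the 8 largest falls, 4 were maltase genes, whose products digest sugars. Mal-A7 changed by -2.19 ± 0.71, Mal-A8 by -1.92 ± 0.54, Mal-A6 by -1.65 ± 0.45 and Mal-A1 by -1.54 ± 0.54, with uncertain counts among related copies. None of these 4 calls held without virgin 2, where adjusted p-values were 0.101, 0.0699, 0.0594 and 0.127. Mal-A1 (adjusted p = 0.0472) was also lost without virgin 1, virgin 3, M1, M3, P1 or P3, with adjusted p-values of 0.0569 to 0.0938, and Mal-A7 without virgin 3, M2 or P1, with 0.0536 to 0.0771. CG4363 changed by -1.20 ± 0.36, and its adjusted p was 0.0741 without virgin 2. Ilp8, the relaxin-like hormone gene (FBgn0036690, 3L:17029812-17032080), fell from 97.7 ± 6.39 to 42.8 ± 10.1 CPM, and lncRNA:CR43250 changed by -1.29 ± 0.20.

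All 3 yolk protein genes rose, as they did when adjusted over the list alone, with a median log2 change of 1.87. Yp2 (FBgn0005391, X:10050951-10052636) rose by 2.21 ± 0.27 and Yp3 (FBgn0004047, X:13759546-13761547) by 1.87 ± 0.35. The list was called by camera (adjusted p = 0.017; adjusted p = 0.36 with an estimated correlation) and by fry (adjusted p = 0.0019). Of 24 eggshell genes, which encode vitelline membrane and chorion proteins, 20 rose, 0 fell and 4 did not pass, with a median of 2.89. Adjusted over the list alone, 22 rose. The chorion gene Cp38 rose from 461 ± 23.04 to 2662 ± 791 CPM, the eggshell assembly gene dec (FBgn0000427) from 251 ± 109.5 to 2225 ± 501 and Vm26Ac (FBgn0086266) from 2.93 ± 0.999 to 25.5 ± 5.95. Camera called the list (adjusted p = 6.9e-10; adjusted p = 0.34 with an estimated correlation), as did fry (adjusted p = 2.4e-04). Germline and maternal genes fell in 22 of 34 cases and rose in 2, also when adjusted over the list alone, with a median of -0.33. The piRNA pathway gene krimp changed by -0.86 ± 0.12, bam by -0.83 ± 0.12, stg by -0.49 ± 0.07 and bcd by -0.46 ± 0.07. Camera gave an adjusted p of 3.3e-05 for a decrease (adjusted p = 0.34 with an estimated correlation) and fry 0.0033.

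**Figure D1:**
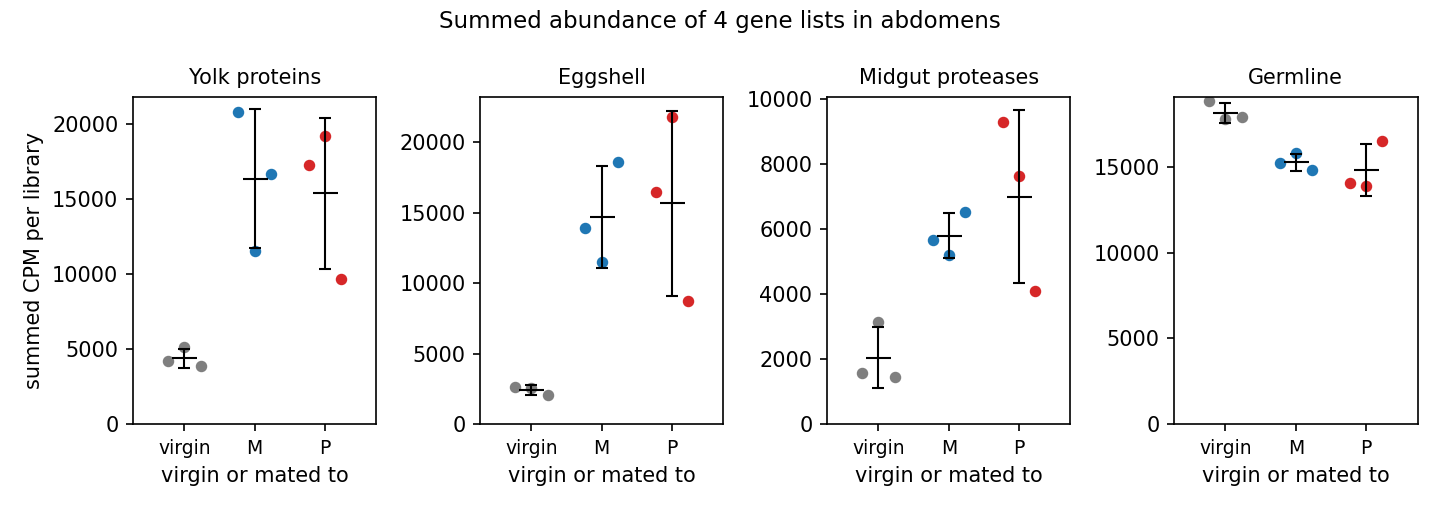
Summed expression (CPM, vertical axes) of the yolk, eggshell, midgut protease and germline lists in each abdomen library, by group; points are libraries, horizontal marks are means and bars are SD. The yolk list averaged 4382 CPM in virgins and 15845 in mated females, and the germline list 18193 and 15069.

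Markers of other tissues moved with mating as well. Of 23 muscle genes, 19 rose and 0 fell (20 adjusted over the list alone), with a median of 1.01 and an adjusted p from camera of 1.4e-08 (adjusted p = 0.34 with an estimated correlation; fry 3.8e-04). The muscle actin gene Act87E rose from 58.7 ± 9.34 to 184 ± 20.02 CPM, Act57B by 1.27 ± 0.11 and the sarcomere gene Zasp66 by 1.09 ± 0.10. Of 11 renal tubule genes 9 rose and 0 fell (11 adjusted over the list alone), with a median of 0.68 that was -0.24 under the muscle and tubule scaling. The urate oxidase gene Uro rose from 16.8 ± 2.13 to 79.7 ± 16.3 CPM. The tubule list had an adjusted p of 0.0010 by camera (adjusted p = 0.34 with an estimated correlation) and 2.8e-04 by fry. Summed expression of the muscle list was 1848 ± 185 CPM in virgins and 3531 ± 219 in mated females.

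Most midgut protease and bomanin genes and 7 of 13 antimicrobial peptide genes rose in mated abdomens, while other genes of digestion and genes of immune recognition went both ways. Of 27 midgut proteases 24 rose and 0 fell (25 adjusted over the list alone), with a median of 1.83. The chymotrypsin-like gene yip7 rose from 251 ± 125 to 941 ± 265 CPM, Jon44E by 1.89 ± 0.35 and deltaTry by 2.09 ± 0.44. The list had an adjusted p of 8.5e-07 by camera (adjusted p = 0.43 with an estimated correlation) and 0.0072 by fry. Amylases, maltases, lipases and lysozymes went both ways, with 7 of 26 higher and 4 lower (6 and 2 adjusted over the list alone). Their median of 0.25 was -0.66 under the muscle and tubule scaling, and camera did not call them (adjusted p = 0.34, and 0.0446 without virgin 2; fry 0.25). The lysozyme gene LysB rose by 3.93 ± 0.58 and the near-identical LysD and LysE by 2.11 ± 0.42 and 1.85 ± 0.36, with uncertain assignment of reads among them. Of 13 antimicrobial peptide genes 7 rose and 0 fell, also when adjusted over the list alone, with a median of 2.20 and an adjusted p of 0.0015 by camera (adjusted p = 0.34 with an estimated correlation; fry 0.0011). AttA (FBgn0012042) rose from 0.553 ± 0.0852 to 14.1 ± 6.76 CPM, Def by 2.11 ± 0.25 and Drs by 0.76 ± 0.16 (-0.18, not past the threshold, under the muscle and tubule scaling), while Mtk did not pass (1.18 ± 1.21, adjusted p = 0.433, and 0.0227 without virgin 3). Of 14 bomanin and daisho genes, short peptides induced by Toll signalling, 13 rose and 0 fell, also when adjusted over the list alone. Their median was 1.26, with an adjusted p of 1.3e-05 by camera (adjusted p = 0.34 with an estimated correlation) and 2.4e-04 by fry. BomS3 rose from 21.6 ± 2.06 to 57.5 ± 12.8 CPM and BomS1 by 1.87 ± 0.23. Of 33 genes of immune recognition and signalling 22 rose and 6 fell (23 and 6 adjusted over the list alone), with a median of 0.81 that was -0.13 under the muscle and tubule scaling. Their adjusted p was 0.0057 by camera (adjusted p = 0.34 with an estimated correlation) and 3.9e-04 by fry. The summed level of this list was lower in every mated library (1721 to 1880 CPM) than in any virgin library (1972 to 2030), and its abundant members cact and spz, named after their values were seen, changed by -0.46 ± 0.07 and -0.61 ± 0.10.

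Most genes of the juvenile hormone, spermathecal, neuropeptide and clock lists also changed in abdomens. Of 12 juvenile hormone genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.46 that was -0.47 under the muscle and tubule scaling. The esterase gene Jhe (FBgn0010052, 2R:16119793-16122773) rose from 0.717 ± 0.272 to 2.46 ± 0.296 CPM and the hormone response gene Kr-h1 by 1.21 ± 0.18. The list had an adjusted p of 0.0057 by camera (adjusted p = 0.34 with an estimated correlation) and 3.9e-04 by fry. Of 9 spermathecal secretory genes, expressed in the sperm storage organs, 7 rose and 0 fell, also when adjusted over the list alone. Send2 rose by 3.36 ± 0.33 and CG17239 by 1.32 ± 0.10; the median was 0.97, with an adjusted p of 0.0010 by camera (adjusted p = 0.34 with an estimated correlation) and 2.4e-04 by fry. Of 34 neuropeptide and amine genes 21 rose and 0 fell, also when adjusted over the list alone, with a median of 0.77 that was -0.15 under the muscle and tubule scaling. The sex peptide receptor gene SPR (FBgn0029768) rose from 15.3 ± 3.22 to 33.7 ± 3.53 CPM, the octopamine synthesis gene Tbh by 1.69 ± 0.20 and ITP by 1.12 ± 0.13. The list had an adjusted p of 6.8e-05 by camera (adjusted p = 0.34 with an estimated correlation) and 4.5e-04 by fry. Of 9 clock genes 7 rose and 1 fell, also when adjusted over the list alone, with a median of 0.62 that was -0.33 under the muscle and tubule scaling. Clk rose by 1.12 ± 0.13, and cyc fell by 0.59 ± 0.06. The clock list had an adjusted p of 0.044 by camera (adjusted p = 0.34 with an estimated correlation) and 9.1e-04 by fry, and the camera call was lost without virgin 1 (adjusted p = 0.0549) or M1 (adjusted p = 0.0557).

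**Figure D2:**
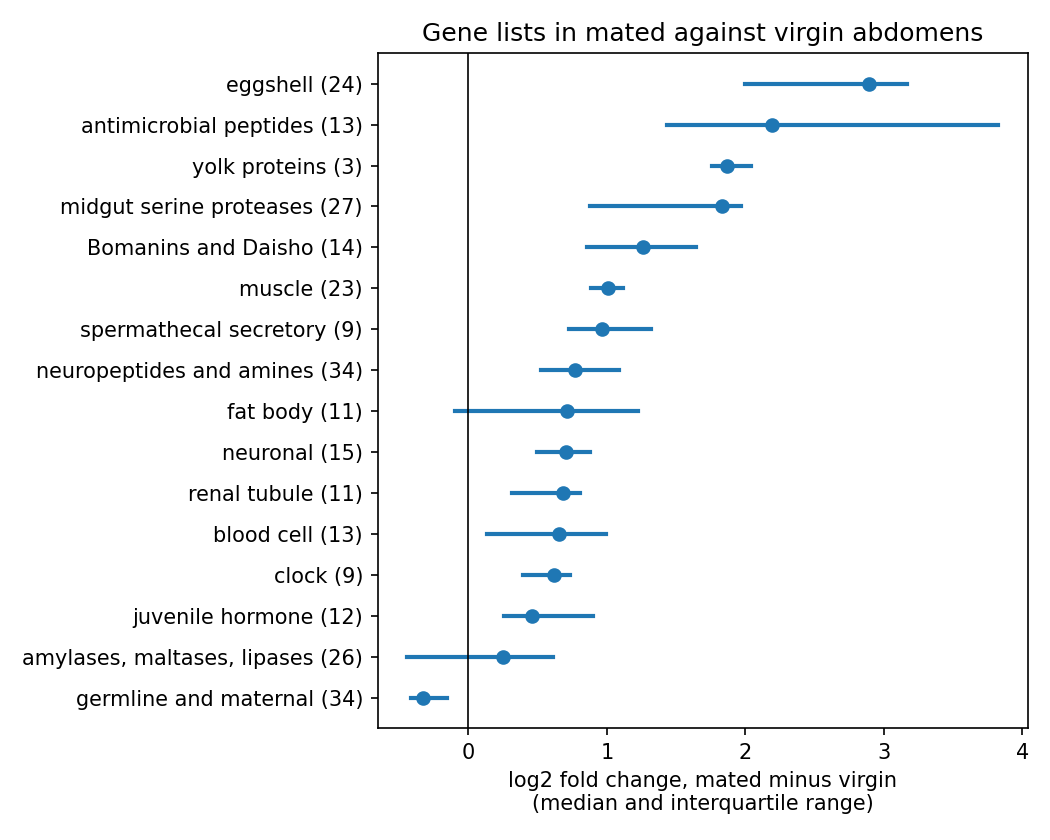
Median log2 change of mated minus virgin abdomens (horizontal axis) for 16 gene lists, with bars from the lower to the upper quartile of their members; each point is the median over the tested genes of a list. The eggshell list stood at 2.89 and the germline list at -0.33; under the muscle and tubule scaling the clock, neuropeptide, juvenile hormone, tubule and other lists with medians of up to 0.81 turned negative.

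Females mated to males of either regime were each compared with the same virgins. In abdomens 4700 genes differed with monogamous males (2526 higher, 2174 lower) and 4927 with polygamous males (2684 higher, 2243 lower). Under the muscle and tubule scaling most genes called with monogamous males were lower, so the balance of rises and falls again depended on the scale. The comparisons shared 2239 higher and 1935 lower genes, where 655 and 471 would be shared by independent lists, and 0 genes went opposite ways. Simulated groups of either tissue, virgins included, were drawn from a common mean. Few genes could then pass, so the 0 shared genes in simulations cannot show how many calls come from shared virgins. Across genes the changes correlated with r = 0.934 against 0.508 in the simulations, and the covariance was 0.668 against 0.0426; genes are not independent replicates. In heads 108 genes differed with monogamous males (43 higher, 65 lower) and 150 with polygamous males (62 higher, 88 lower). Of these, 29 were shared as higher and 49 as lower, against 0.245 and 0.525 for independent lists and 0 in simulations, with r = 0.253 across genes against 0.517 and a covariance of 0.0722 against 0.0857, both below the simulated values. With 3 virgin libraries per tissue the controls could not be split, and part of the shared calls may come from sharing them. The monogamous count in abdomens was 2987 without M3. In heads it was 12 without M2, 16 without M1, 21 without virgin 1, 30 without virgin 3, 34 without P1 and 42 without M3, and the polygamous count was 11 without P1, 20 without P2, 26 without virgin 1, 33 without virgin 3 and 314 without P3.

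In heads, mating was followed by a higher level of the juvenile hormone esterase gene and by lower levels of several genes of the circadian clock. Jhe rose from 1.37 ± 0.0142 CPM in virgins to 10.9 ± 3.10 in mated females, a log2 change of 2.98 ± 0.17 (adjusted p = 8.6e-05). The clock gene tim (FBgn0014396, 2L:3493986-3508119) fell from 383 ± 36.4 to 137 ± 25.97 CPM, and the odorant binding protein gene Obp99b (FBgn0039685) from 6.52 ± 1.76 to 1.75 ± 0.463. Thor, which encodes the translation repressor 4E-BP (FBgn0261560), rose from 241 ± 39.5 to 491 ± 78.8 CPM. In all, 241 of 10886 genes (2.21%) differed, 94 higher and 147 lower, with 1708 genes at an unadjusted p below 0.05 against 544.3 expected by chance; 15 rose and 14 fell at least 2-fold. The groups did not overlap for 937 genes (8.61%), 232 of them called, against 2.38% by chance.

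Midgut protease transcripts were high in 3 of the 9 head libraries: virgin 1 (9033 CPM in sum), M1 (7102) and M2 (14513), against 12.4 to 100.3 in the other 6. These libraries came from virgin and monogamous groups. In mated minus virgin heads, 0 of 19 midgut proteases passed; their median log2 change was -1.72 and mean -1.58, while the direction of the camera test was upward (adjusted p = 0.67; adjusted p = 0.93 with an estimated correlation). KappaTry, Ser6, thetaTry and alphaTry had changes of -3.72 ± 2.02, -4.01 ± 2.43, -1.72 ± 1.25 and -3.40 ± 2.48, none of which passed, and without virgin 1 all 4 were above 0 (2.98, 7.32, 1.21 and 5.50). Without virgin 1 camera gave the list an adjusted p of 0.00261, and without M3 0.0486. With virgin 1, M1 and M2 left out together, a choice made after the data were seen, 0 genes were called by edgeR in heads, with 961 genes at an unadjusted p below 0.05. That omission left M3 as the only M library, beside virgin 2, virgin 3 and the P libraries. With the protease level as a covariate, also added later, 235 genes were called, 208 of them among the 241.

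**Figure D3:**
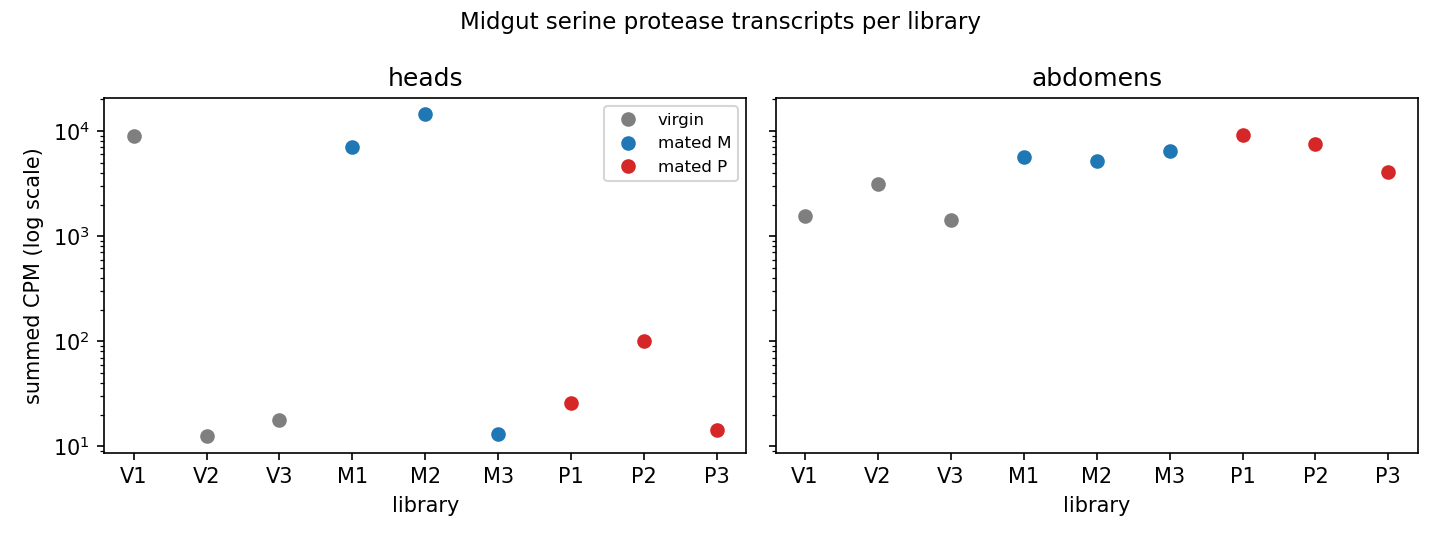
Summed expression of midgut proteases (CPM, log vertical axis) in each library of both tissues, by group; points are libraries. Head libraries virgin 1, M1 and M2 lay at 9033, 7102 and 14513 CPM, above the abdomen mean of 4941, and the other head libraries at 12.4 to 100.3.

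The number of genes called in heads depended on single libraries. It was 77 without virgin 3, 79 without virgin 1, 89 without P1, 136 without P2, 137 without M1 and 153 without M2. DESeq2 called 626 genes and limma voom 156.

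Among clock genes in heads, 2 of 9 rose, 4 fell and 3 did not pass; adjusted over the list alone 3 rose and 4 fell. Clk (FBgn0023076) rose from 43.0 ± 2.83 to 77.7 ± 6.39 CPM, a change of 0.85 ± 0.08, and the repressor gene vri (FBgn0016076) fell from 217 ± 27.6 to 100.1 ± 13.6. Pdp1 (FBgn0016694) changed by -0.80 ± 0.08. Of genes named after their values were seen, per (FBgn0003068) changed by -0.63 ± 0.09 (adjusted p = 0.0082) and cry (FBgn0025680) by 0.41 ± 0.09 (adjusted p = 0.041), and cwo did not pass (0.25 ± 0.09, adjusted p = 0.23). Camera did not call the list (adjusted p = 0.41; adjusted p = 0.88 with an estimated correlation), and fry gave 0.12 for movement one way and 3.6e-05 for change in either direction. The calls of tim, Clk, vri and Pdp1 held without each library in turn, with adjusted p-values of at most 0.0147. With virgin 1, M1 and M2 left out together none of the 4 passed, with changes of -1.60, 0.74, -1.08 and -0.85 (adjusted p-values of 0.0607 to 0.0881). Midgut proteases differed between libraries within both groups, and tim changed by -1.48 with their level as a covariate.

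**Figure D4:**
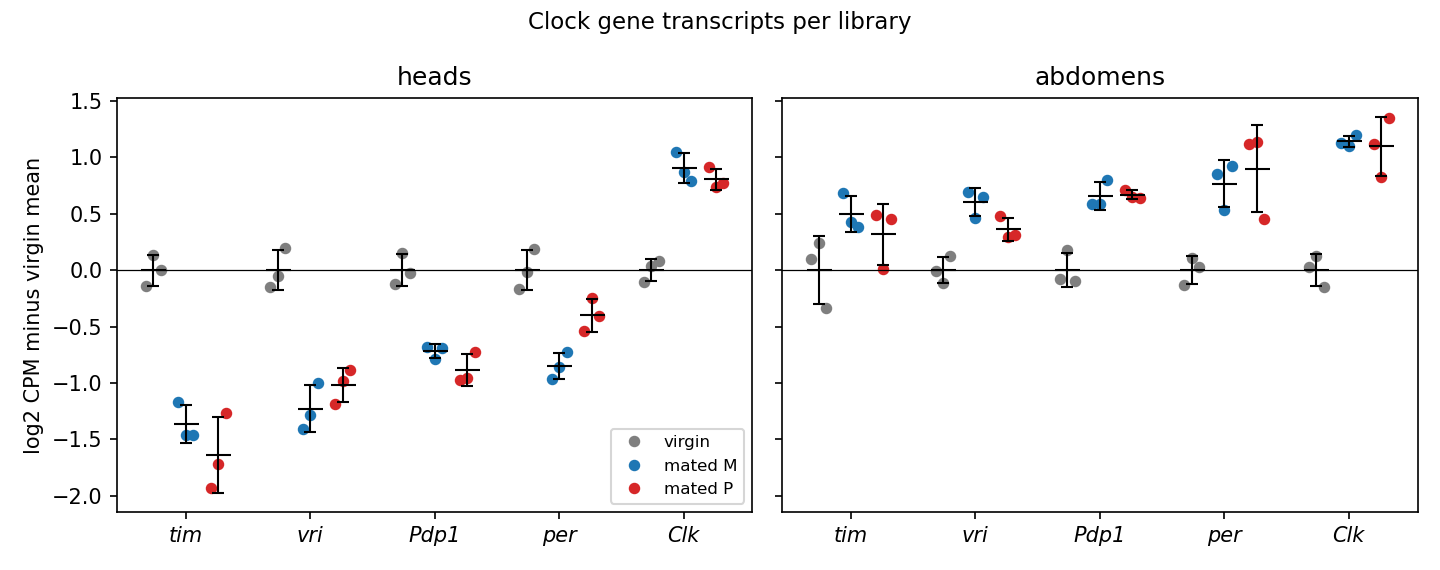
Log2 CPM minus the virgin mean (vertical axis) of tim, vri, Pdp1, per and Clk in heads and abdomens; points are libraries, with means and SD bars per group. In heads tim changed by -1.49 and Clk by 0.85; in abdomens tim, vri and per rose by 0.40, 0.48 and 0.85, and under the muscle and tubule scaling the median of the clock list in abdomens was -0.33.

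Other named rises in heads were Cyp304a1 (FBgn0038095; 1.62 ± 0.21), CG16743 (1.52 ± 0.20), CG18327 (1.33 ± 0.18), CG43448 (1.28 ± 0.17), CG3348 (1.24 ± 0.26), Root (1.15 ± 0.22) and the arginase gene arg (1.13 ± 0.10). Other falls were Lcp65Ag2 (-1.56 ± 0.20), CG18302 (-1.34 ± 0.14), Cyp309a1 (-1.29 ± 0.19), snsl (-1.21 ± 0.13), asRNA:CR45144 (-1.16 ± 0.24, with uncertain strand) and Cpr60D (-1.13 ± 0.15). The calls of Jhe, arg, CG18327, CG43448, Obp99b, Lcp65Ag2, CG18302, snsl and Cpr60D held without each library in turn, though none without virgin 1, M1 and M2 together. Cyp304a1 was not called without virgin 1 (adjusted p = 0.0543) or virgin 3 (adjusted p = 0.0624), and CG16743 without virgin 3 (adjusted p = 0.0736). Cyp309a1 was lost without virgin 1, virgin 3, M3, P1 or P2, with adjusted p-values of 0.0509 to 0.0965. With 1 library left out, CG3348 kept its call only without M3 or P3, Root only without P3 and asRNA:CR45144 only without P1; their adjusted p-values otherwise reached 0.188, 0.169 and 0.161.

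Yolk protein genes, which are expressed in fat body of the head, had a median of 0.58 in heads. Yp2 rose from 13159 ± 1954 to 26027 ± 5042 CPM, while Yp1 (0.36 ± 0.12) and Yp3 (0.58 ± 0.18) did not pass; adjusted over the list alone all 3 rose. The adjusted p was 0.019 by camera (adjusted p = 0.88 with an estimated correlation) and 0.12 by fry, and that of Yp2 was 0.0519 to 0.145 without virgin 1, virgin 3, M1, M2, M3 or P1. Of 32 odorant binding protein genes 3 rose and 4 fell (4 and 5 adjusted over the list alone), with a median of 0.12 and a mean of -0.04; camera gave an adjusted p of 0.58 (adjusted p = 0.88 with an estimated correlation) and fry 3.5e-08 for change in either direction. Obp49a rose by 0.54 ± 0.08, Obp56h by 0.57 ± 0.09 and Obp83ef by 0.93 ± 0.15, and without virgin 3 these were not called (adjusted p-values of 0.0573, 0.0809 and 0.0967). Obp56h and Obp83ef were also lost without virgin 1 (0.0882 and 0.087) and Obp83ef without P1 (0.0555). Besides Jhe, no other gene of 13 in the juvenile hormone list passed, although 2 rose when adjusted over the list alone. Its median was 0.01, with an adjusted p of 0.29 by camera (adjusted p = 0.88 with an estimated correlation) and 0.069 by fry. Of 72 cytochrome P450 genes 8 fell and 1 rose (14 and 2 adjusted over the list alone), with a median of -0.15, and Cyp309a2 changed by -0.84 ± 0.10. Camera gave an adjusted p of 0.0022 (adjusted p = 0.88 with an estimated correlation; fry 0.34), and 0.210 without virgin 1. In the insulin and FOXO list Thor and rictor (0.35 ± 0.07) rose among 18 genes and 0 fell (4 rose and 2 fell adjusted over the list alone), with a median of 0.15. Camera gave an adjusted p of 0.021 (adjusted p = 0.88 with an estimated correlation; fry 0.12), and 0.152 without virgin 1, without which Thor had an adjusted p of 0.087 and rictor of 0.116. Thor was also lost without virgin 3 (0.0593), and rictor without virgin 2, virgin 3, M1, M2, P1 or P2 (0.0512 to 0.078).

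Several further lists in heads had small medians, and no or few of their members were called. Cytosolic ribosomal protein genes had 0 of 82 members past the threshold, also when adjusted over the list alone, 75 changes above 0 and a median of 0.19. RpS2 had 688 ± 63.7 CPM in virgins and 879 ± 140.0 in mated females (0.35 ± 0.12, adjusted p = 0.181). Camera called the list (adjusted p = 1.9e-09; adjusted p = 0.88 with an estimated correlation), and fry did not (0.57). Genes of oxidative phosphorylation had 0 of 69 called and a median of 0.06, with an adjusted p of 0.033 by camera (adjusted p = 0.88 with an estimated correlation; fry 0.83) and the call was lost without virgin 1, virgin 2, M1, P1 or P2 (adjusted p-values of 0.0672 to 0.681). The 14 mitochondrially encoded genes had 0 called, 13 changes below 0 and a median of -0.36, and 10 fell when adjusted over the list alone. The mitochondrial gene mt:ND4 changed by -0.46 ± 0.12 (adjusted p = 0.098). Camera gave an adjusted p of 6.1e-05 (adjusted p = 0.88 with an estimated correlation; fry 0.14). Of 25 photoreceptor genes 3 fell and 0 rose (6 and 3 adjusted over the list alone), with a median of -0.07 and no call by camera (adjusted p = 0.44; adjusted p = 0.88 with an estimated correlation). The carotenoid uptake gene ninaD changed by -0.66 ± 0.10 and the phospholipase gene norpA by -0.40 ± 0.08, and the call of ninaD was lost without virgin 3 (adjusted p = 0.056) and that of norpA without any library but P3 (0.0501 to 0.119). Of 37 cuticle protein genes 1 rose and 4 fell (2 and 8 adjusted over the list alone), with a median of -0.18; camera gave an adjusted p of 0.22 (adjusted p = 0.88 with an estimated correlation) and fry 2.4e-08 for change in either direction. TwdlT rose by 0.94 ± 0.13, and Cpr65Au changed by -0.44 ± 0.07 and was not called without virgin 1 (adjusted p = 0.0681). Mtk, Drs and AttA did not pass in heads (-0.98 ± 1.33, 0.27 ± 0.90 and 0.32 ± 0.73). Of 10 antimicrobial peptide genes 0 passed, also when adjusted over the list alone; the median of -0.22 and mean of -0.33 were below 0 while the direction of camera was upward (adjusted p = 0.40; adjusted p = 0.88 with an estimated correlation; fry 0.83). Virgin 3 held 638 CPM of this list against 165 and 169 in the other virgins, and without it camera called the list (adjusted p = 1.5e-04) and Mtk was at 2.48, which did not pass. Drs was below 0 without virgin 1 (-0.02), virgin 2 (-0.03), M3 (-0.11) or P1 (-0.06), and AttA without virgin 1 (-0.12).

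The effect of the males' regime was tested by comparing P with M females. In abdomens 0 of 10350 genes passed in edgeR, and the smallest adjusted p was 0.9998. An unadjusted p below 0.05 was found for 185 genes, fewer than the 517.5 expected by chance. With M1, P1 and P2 set against the other mated abdomens 93 genes were called, a difference between libraries that was not tested further. DESeq2 called 14 genes (4 higher, 10 lower) and limma voom 0. The groups did not overlap for 570 genes (5.51%), where chance gives 10% with 3 libraries against 3. Without M1, 79 genes were called, all lower in P females, and with the muscle and tubule scaling 28 were called (13 higher, 15 lower). The 5 genes with the smallest unadjusted p were asRNA:CR45192 (1.27 ± 0.27, with uncertain strand), the mucin gene Muc26B (-4.21 ± 0.85), the apoptosis gene Arts (-0.57 ± 0.12) and the cuticle genes Cpr92F (-2.03 ± 0.45) and Cpr11A (-3.55 ± 0.77), none of which passed. Without M1, Muc26B (adjusted p = 1.6e-04), Cpr11A (0.0018) and Cpr92F (0.0412) did. Arts (FBgn0042177) had 209 ± 18.9 CPM with monogamous and 141 ± 13.1 with polygamous males (n = 3 each). In data simulated for this comparison, 83.6% of genes changed 2-fold and 38.8% of genes changed 1.5-fold were called, all with a mean log2 CPM of at least 1. Genes were drawn independently there, so differences between libraries shared by many genes were left out. Many genes were also changed in the same simulation, which eases the adjusted threshold for each of them. Fewer changed genes were not simulated, so these shares do not show how often a regime effect on few genes would be called.

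All 14 bomanin and daisho genes had changes above 0 in abdomens of P females, with 0 past the threshold over all genes and 2 when adjusted over the list alone. The median was 0.33 (0.27 under the muscle and tubule scaling), and BomS3 had 47.6 ± 5.50 CPM in M and 67.4 ± 9.32 in P females (0.50 ± 0.12). Camera gave an adjusted p of 4.1e-09 (adjusted p = 0.46 with an estimated correlation), and fry 0.93. Neuronal genes had a median of -0.40 with 13 of 15 below 0 (camera adjusted p = 3.0e-05; adjusted p = 0.77 with an estimated correlation; fry 0.93). Gad1 changed by -1.30 ± 0.46 and brp by -0.74, neither of which passed. Glutathione transferases had a median of 0.10 with 25 of 34 above 0 (camera adjusted p = 0.0017; adjusted p = 0.77 with an estimated correlation; fry 0.93), and the call was lost without P2 (adjusted p = 0.0779). GstE1 had 91.3 ± 7.93 CPM in M and 122 ± 16.2 in P females. The 5 Turandot stress genes were all below 0, with a median of -1.03 (camera adjusted p = 0.011; adjusted p = 0.77 with an estimated correlation), and the call was lost without M1 (adjusted p = 0.155), M2 (0.383), P1 (0.114) or P2 (0.323). TotA and TotC, which are similar in sequence, had changes of -1.11 ± 1.35 and -1.03, and that of TotA was 0.00499 without M2. Midgut proteases had a median of 0.26 with 26 of 27 above 0 (camera adjusted p = 0.013; adjusted p = 0.81 with an estimated correlation), lost without M1 (adjusted p = 0.101), M2 (0.300), P2 (0.227) or P1, where the direction turned (0.840). For cuticle proteins the median of 0.03 and the mean of -0.33 differed in sign, and the camera call for a decrease (0.022; adjusted p = 0.77 with an estimated correlation) was lost without M2 (0.167) or M3 (0.163). Camera called 11 of 35 lists in this comparison (7 up, 4 down), and neither fry nor the estimated correlation called any of them.

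In heads 0 of 10886 genes passed in edgeR between P and M, and the smallest adjusted p was 0.614. An unadjusted p below 0.05 was found for 864 genes, against 544.3 expected by chance. DESeq2 called 17 genes (5 higher, 12 lower) and limma voom 0. The groups did not overlap for 1653 genes (15.2%, against 10% by chance). The chitinase-like gene Idgf3 (FBgn0020414) had the smallest unadjusted p, with 101 ± 3.15 CPM in M and 70.9 ± 2.39 in P females (n = 3 each; -0.51 ± 0.08). It was followed by mdy (-0.44 ± 0.08), Ilp7 (1.86 ± 0.35), CG5828 (0.46 ± 0.09) and CG11122 (0.43 ± 0.09), and none passed. Midgut proteases had a median of -7.42 with 18 of 19 below 0, with M1 and M2 the mated head libraries highest in these transcripts. Jon25Bii had 83.0 ± 78.7 CPM in M and 0.153 ± 0.219 in P females, a change of -9.19 ± 2.95 that did not pass. With virgin 1, M1 and M2 left out together, which leaves M3 as the only M library, the list median was 1.54. Jon25Bii (2.57), Jon25Bi (0.62), Jon99Ciii (0.77) and Jon99Cii (0.71) were then above 0. In these remaining libraries the list summed to 13.1 CPM in M3 and to 25.8, 100.3 and 14.5 in P1, P2 and P3. Camera gave an adjusted p of 5.5e-05 (adjusted p = 0.90 with an estimated correlation; fry 0.83). Digestion genes had a median of -2.44 (camera adjusted p = 0.0017, and 0.90 with an estimated correlation). Their sum was 1698 and 2113 CPM in M1 and M2, against 334 to 448 in M3 and the P libraries. Heat shock genes had a median of 0.63 with 16 of 17 above 0 (camera adjusted p = 0.0086; adjusted p = 0.90 with an estimated correlation), lost without M3 (adjusted p = 0.112) or P1 (0.362). Hsp60A changed by 0.35 ± 0.11 and stv by 0.37, and neither passed. All 14 mitochondrially encoded genes were below 0, with a median of -0.16 (camera adjusted p = 0.017; adjusted p = 0.90 with an estimated correlation), lost without M2 (adjusted p = 0.313) or P1 (0.181). The clock list was not called (median 0.07, camera adjusted p = 0.59, adjusted p = 0.90 with an estimated correlation; 1 gene higher adjusted over the list alone), and per had 30.4 ± 2.50 CPM in M and 41.6 ± 4.17 in P females (0.45 ± 0.11, not past the threshold over all genes).

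The response score summarised the mating response of each library over all called genes. In abdomens it was 0.720 ± 0.0592 in M and 0.741 ± 0.0838 in P females (n = 3 each), a difference of 0.0205 (exact 2-sided permutation p = 0.8). In heads it was 0.612 ± 0.0418 and 0.647 ± 0.0808, a difference of 0.0349 (exact p = 0.6), where 3 libraries against 3 give no p below 0.1. The sign of the abdomen difference turned without M1 (-0.0329), M2 (-0.0183) or P1 (-0.00629), and that of the head difference without M3 (-0.0187), P1 (-0.0160) or P2 (-0.00128).

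**Figure D5:**
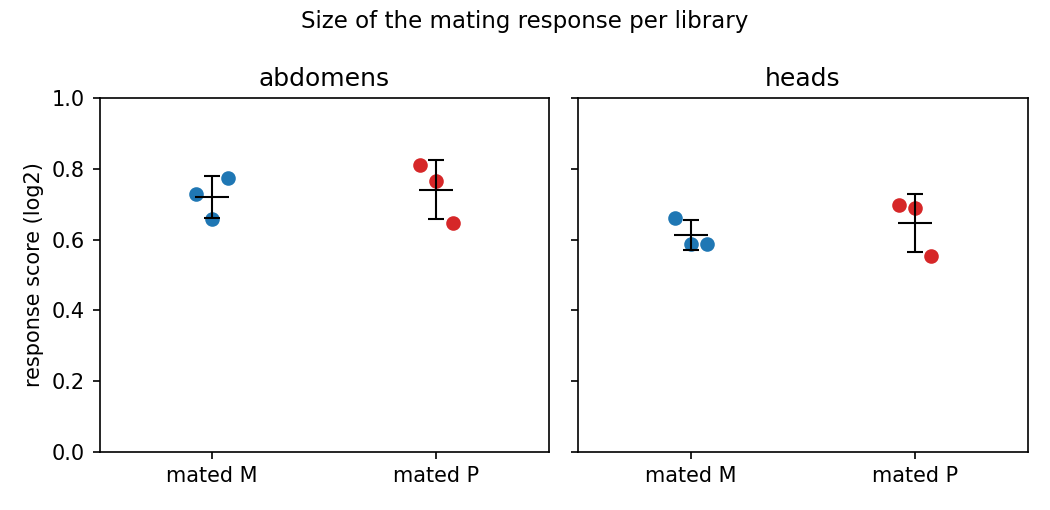
Response score (mean signed log2 difference from virgins over genes called in the mated minus virgin comparison, vertical axis) of each mated library in abdomens and heads, by regime of the males; points are libraries, with means and SD bars. Scores in abdomens were 0.648 to 0.810 and those in heads 0.554 to 0.697, with M and P libraries overlapping in both tissues.

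The mating effect differed between tissues for 4326 of 11631 genes, 2163 more positive and 2163 more negative in abdomens than in heads, with 5508 genes at an unadjusted p below 0.05. Differences of at least 2-fold were 992 and 42. The largest were sit (FBgn0038986, 3R:22558342-22562572), a fatty acid elongase gene, with 7.71 ± 0.67, and CG3739 (7.08 ± 1.96), Fcp3C (5.51 ± 0.58), Fst (5.30 ± 1.77) and CG43774 (5.29 ± 1.56). In the other direction were bam (-3.44 ± 0.70), CG9503 (-2.67 ± 0.73), Hsp27 (-2.54 ± 0.86), dpr16 (-2.45 ± 0.75) and asRNA:CR44018 (-2.36 ± 0.76). With each library left out in turn, the calls of sit, Fcp3C and bam held. Without head virgin 1 the difference was 0.0836 for CG3739 (adjusted p = 1.00), 0.19 for CG43774 (adjusted p = 0.955), 2.59 for Fst (adjusted p = 0.404) and -2.10 for CG9503 (adjusted p = 0.0538). Fst was also lost without head P1 or any 1 of the virgin abdomens (0.0525 to 0.0768), and CG43774 without abdomen virgin 3 (0.0533). Hsp27 was lost without head virgin 1, virgin 2, P1 or P2 or abdomen virgin 3, M2, M3 or P1 (0.0501 to 0.0819). The call of dpr16 was lost without abdomen virgin 2 (-0.996, adjusted p = 0.434), M3, P1, P2 or P3 (0.0534 to 0.0595), and that of asRNA:CR44018 without abdomen virgin 1 (adjusted p = 0.185) or M1 (0.0507). Sit changed by 7.15 in abdomens and by -0.65 in heads. CG3739, bam and CG9503 were below the expression filter in heads, and dpr16 and asRNA:CR44018 in abdomens. Clock genes, and Jhe, were named here after their values were seen. The mating effect differed between tissues for tim by 1.82 ± 0.23 (adjusted p = 7.8e-05), vri by 1.54 ± 0.16, Pdp1 by 1.40 ± 0.13 and per by 1.41 ± 0.21, while the difference did not pass for Clk (0.20, adjusted p = 0.25). The muscle and tubule scaling was not applied to this model, so the counts of genes and the balance of directions were not tested under it. It moved the median of all genes in mated minus virgin abdomens to -0.90, and the direction of clock changes there depended on it. Under that scaling Pdp1 and cwo changed in abdomens by -0.28 and -0.33, neither past the threshold. Jhe rose more in heads (-1.27 ± 0.29, adjusted p = 0.0038). The count of calls was 2815 without head libraries virgin 1, M1 and M2.

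The regime effect differed between tissues for 0 genes in edgeR, with 741 at an unadjusted p below 0.05 against 581.55 expected by chance. The smallest adjusted p was 0.409, and DESeq2 called 23 and limma voom 0. The smallest unadjusted p belonged to the cuticle gene Cpr49Ag (-5.54 ± 0.97) and to asRNA:CR45192 (3.92 ± 0.73, with uncertain strand), followed by CG8343 (-0.86 ± 0.18), CG8910 (-1.70 ± 0.37) and Octbeta1R (-1.62 ± 0.35), none of which passed. Without abdomen virgin 1, CG8910 did (adjusted p = 0.0150). Without abdomen M1, 46 genes were called, Cpr49Ag among them (-6.06, adjusted p = 5.5e-05).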

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

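The covariate test of the clock genes, the test of mixed abdomen RNA in heads, the 3 tests of ovary share and the comparison of male transcripts with the muscle list were chosen after the results they bear on had been seen.

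Under TMM normalisation, muscle, renal tubule, fat body, blood cell and neuronal lists had higher medians in mated than in virgin abdomens and the germline list a lower one, although the summed neuronal level was 556 ± 19.03 CPM in virgin and 470 ± 48.2 in mated abdomens. The fat body and neuronal medians under the muscle and tubule scaling are not reported here. A lower share of ovary RNA would raise somatic markers alike, but within libraries 2 of 4 somatic lists moved apart from muscle, tubule by -0.37 and blood cell by -0.40 (exact 2-sided permutation p = 0.0238 for both), with neuronal at -0.56 (p = 0.0714) and fat body at -0.37 (p = 0.107) and values of 0.0595 to 0.119 when adjusted over the 10 lists compared. Such a share as a part of the rise cannot be told apart from responses of each tissue to mating, which stay open, since expression of the members in the ovary was not tested. The tables argue against it for eggshell genes, made in follicle cells of the ovary, which rose by 1.72 relative to muscle (exact p = 0.0119, the smallest that 6 libraries against 3 allow; 0.0595 adjusted over the 10 lists) and of which 20 of 24 passed in edgeR. For midgut proteases, with 0.54 relative to muscle (exact p = 0.0595), a lower ovary share and a rise in the midgut itself cannot be told apart because the exact test did not pass. Relative to muscle, the yolk list rose by 0.80 (exact p = 0.0357), antimicrobial peptides by 1.19 (0.0595) and bomanin and daisho genes by 0.23 (0.167). Adjusted over the 10 lists these p-values were 0.0714 to 0.167.

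Midgut protease transcripts reached 9033 CPM in virgin 1, 7102 in M1 and 14513 in M2 among head libraries, against 12.4 to 100.3 in the other 6; alphaTry was at 2844, 932.5 and 2279 CPM, against 1.39 to 19.7. Mixing of abdomen RNA into these heads was argued against, since the lowest of the 3 was 1.44 times the abdomen mean of 4941 CPM while the germline list stood at 4.88% to 5.03% of its abdomen mean, within the 4.66% to 5.28% of the other heads. Midgut tissue carried over with some heads remains a candidate explanation: the digestion list, a separate set of midgut products, was highest in the same 3 of 3 libraries (3922, 1698 and 2113 CPM, against 330.0 to 448 in the others). Effects of mating or of the males' regime on these transcripts were not tested apart from such carry-over and stay open.

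In mated heads tim, vri and Pdp1 fell and Clk rose. Midgut RNA in some head libraries was argued against as the cause, as tim changed by -1.48 with the midgut protease level as a covariate and by -1.49 without it; with virgin 1, M1 and M2 left out together it changed by -1.60 and no longer passed (adjusted p = 0.0881 in edgeR). Freezing of mated and virgin females at different clock times would lower per and cwo and raise cry. Of these 3 genes 2, per (-0.63 ± 0.09) and cry (0.41 ± 0.09), changed that way. The change of cwo was above 0, the other way, and did not pass (0.25 ± 0.09, adjusted p = 0.23 in edgeR). A difference in clock time and an effect of mating cannot be told apart, because the time of day of freezing is not given in the sources used here. The difference between tissues, 1.82 ± 0.23 for tim (adjusted p = 7.8e-05 in edgeR), was not tested against either explanation. It was also not tested under the muscle and tubule scaling, where Pdp1 changed by -0.28 in abdomens.

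Counts of called genes were set against those from other splits of the same libraries. For mated minus virgin abdomens the labelled split alone, 1 of 84, reached 5608 genes and the highest other called 181, so chance is argued against. Whether the virgin pools came from separate cultures is not given, and the splits do not test this. For mated minus virgin heads the labelled split was also the only 1 of 84 to reach 241, a share below the 0.05 set beforehand. Another split called 232, and it put virgin 1, M1 and M2, the libraries rich in midgut transcripts, together. The margin was narrow and the labelled count was 77 without virgin 3, so chance is argued against but not excluded. For the difference in mating effect between tissues 1 of 100 splits drawn from 7056, the labelled one, reached 4326. The highest other, with 3734, kept the real abdomen labels. Labels were shuffled in both tissues, so these splits test for a mating effect in either tissue and cannot decide on chance for the difference. For the difference in regime effect the real count was 0 in edgeR (741 genes at an unadjusted p below 0.05, DESeq2 23, limma voom 0), which all 100 splits reach by construction, so nothing can be read from them about chance. The highest other split called 811 genes and the next 236, which points to some structure of the samples that was not tested further.

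Comparisons of 3 libraries with 3 have 10 splits, too few for a share below 0.05. For abdomens of M minus virgin (4700 called) and P minus virgin (4927) 1 split each reached the real count and the highest other called 0. For heads of P minus virgin (150) this also held for 1 split, with 0 as the highest other. For heads of M minus virgin (108) 2 splits did, and the highest other, 161, again put virgin 1, M1 and M2 together. For P minus M all 10 splits reached the real count of 0 in both tissues in edgeR, as any split must, with 93 as the highest other in abdomens (185 genes at an unadjusted p below 0.05, DESeq2 14, limma voom 0) and 0 in heads (864, 17 and 0).

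Single libraries stood apart from the other 5 mated ones for 10 of 137 groups of 6 examined, where chance gives 6.85. In abdomens, Osi19 was at 10.5 CPM in P2 against 0.522 to 2.93 in the others, and lncRNA:CR43250 at 6.02 in P3 against 2.67 to 3.89. The eggshell gene dec was at 3205 CPM in M1 against 1903 to 2304. The xanthine dehydrogenase gene ry was at 15.8 CPM in P2 against 19.4 to 21.2, and ImpL2 at 236 in M2 against 174 to 196. In heads, CG18327 was at 10.5 CPM in P3 against 15.3 to 18.1, Cyp309a1 at 29.4 in M2 against 16.3 to 21.2 and Obp56h at 48.8 in M3 against 39.4 to 42.2. The midgut proteases Ser6 and thetaTry were at 14.7 and 1.54 CPM in head M2 against 0 to 2.61 and 0.0441 to 0.360.

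The mating effect differed between abdomens and heads for 4326 genes by the interaction test in edgeR, a count that was not tested under the muscle and tubule scaling. The named differences, abdomen minus head on the log2 scale, were 7.71 for sit, 7.08 for CG3739, 5.51 for Fcp3C, 5.30 for Fst and 5.29 for CG43774, and -3.44 for bam, -2.67 for CG9503, -2.54 for Hsp27, -2.45 for dpr16 and -2.36 for asRNA:CR44018. Without head virgin 1, CG3739 was at 0.0836 (adjusted p = 1.00 in edgeR), CG43774 at 0.19 (0.955), Fst at 2.59 (0.404) and CG9503 at -2.10 (0.0538). Without abdomen virgin 2, dpr16 was at -0.996 (adjusted p = 0.434), without abdomen virgin 1 asRNA:CR44018 was at -1.76 (0.185), and Hsp27 lost its call in 8 single omissions, with adjusted p-values of 0.0501 to 0.0819.

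Transcripts of the accessory gland and testis lists were present at low levels in virgin and mated abdomens. The accessory gland list summed to 170 ± 6.59 CPM in virgin heads, so RNA of its members was not limited to males. The accessory gland list summed to 1.05 CPM in mated against 0.650 ± 0.202 in virgin abdomens, and the testis list to 2.22 against 1.13 ± 0.101.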

How the results depend on the processing

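The scaling on muscle and renal tubule genes, the joint omission of head libraries virgin 1, M1 and M2 and the midgut level as a covariate were chosen after the data had been seen; the other alternatives were planned. Of 262 alternative counts of genes 194 lay within 1.5 times the reported count, as did 40 of 48 counts of lists. Of 4680 alternative values of named genes 4334 kept their direction and side of the threshold, 264 lost and 51 gained a call and 31 turned in direction; for 1704 list values these numbers were 1493, 149, 57 and 5. Of 35 alternative response scores 29 kept their sign. Where the cause is not given by the setting itself, as with fewer libraries, a stricter threshold or a minimum fold, the cause was not tested. Depth limited genes near the floor, where 3 counts over the virgin abdomens are 0.0194 CPM. Simulated 1.5-fold changes between P and M were called for 38.8% of genes in abdomens and 37.3% in heads. The changed genes there had a mean log2 CPM of at least 1, so these shares do not describe genes near the floor. Many genes were changed together in these simulations, so the shares also do not describe a regime effect on few genes.

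With a threshold of 0.01 the calls were 3638 (mated minus virgin), 2382 (M minus virgin) and 2743 (P minus virgin) in abdomens, 60, 7 and 19 in heads and 2338 for the difference in mating effect between tissues. At 0.1 they were 483, 168 and 377 in heads. With a minimum of 1.5-fold they were 2636, 2348 and 2512 in abdomens, 96, 66 and 77 in heads and 2289 for the difference between tissues. DESeq2 called 626, 339 and 741 genes in heads, 14 for P minus M in abdomens and 17 in heads, and 23 for the regime effect between tissues. Limma voom called 156, 56 and 87 in heads, and dispersions without the robust step gave 154, 41 and 95. Models with the compared groups alone called 50 (M minus virgin) and 79 (P minus virgin) in heads and 1 for the regime effect between tissues. Run 2 alone called 2808 for the mating effect between tissues. The muscle and tubule scaling called 7416 for mated minus virgin in abdomens (3607 shared with the 5608), 7182 for M minus virgin (432 higher, 6750 lower), 7165 for P minus virgin and 28 for P minus M. With the midgut level as a covariate 1 gene was called for P minus M in heads. The joint omission given next left M3 as the only M library in heads. With head libraries virgin 1, M1 and M2 left out together, edgeR called 0 for mated minus virgin (961 at an unadjusted p below 0.05), 0 for M minus virgin (704) and 0 for P minus virgin (1459) in heads. The same omission gave 1 for P minus M, 1 for the regime effect between tissues and 2815 for the mating effect between tissues.

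Leaving out each library in turn gave 4320 to 6021 calls for mated minus virgin, 2987 (without M3) to 5163 for M minus virgin, 3294 to 5228 for P minus virgin and 0 to 79 (without M1) for P minus M in abdomens. In heads it gave 77 (without virgin 3) to 311 (without P3), 12 (without M2) to 107, 11 (without P1) to 314 (without P3) and 0 to 2 (without M3) in the same order. It gave 3187 to 4634 for the mating effect and 0 to 46 (without abdomen M1) for the regime effect between tissues. The P minus M response score was -0.0329 (without M1) to 0.0855 in abdomens, also turning without M2 (-0.0183) and P1 (-0.00629), and -0.0187 (without M3) to 0.141 in heads, also turning without P1 (-0.0160) and P2 (-0.00128). Lists called numbered 24 to 28 for mated minus virgin and 8 to 16 for P minus M in abdomens, and 5 to 8 and 5 (without P1) to 11 in heads.

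Camera called 27 of 35 lists for mated minus virgin and 11 for P minus M in abdomens, and 6 and 9 of 36 in heads. With an estimated correlation it called 0 in each of these comparisons. Fry called 27 for mated minus virgin in abdomens, 24 of them shared with camera, and 0 for P minus M in abdomens and for both in heads. For P minus M in abdomens, 4 lists turned without a single library. The adjusted p of cytosolic ribosomal proteins was 0.00836 without M2 and 9.04e-04 without P2, between 6.31e-15 (without P3) and 0.709 (without M3). That of mitochondrial ribosomal proteins was 0.00635 without P2 (3.47e-07 to 0.842 over the omissions), that of oxidative phosphorylation 0.0179 without P2 (3.53e-14 to 0.832) and that of midgut proteases 0.840 without P1, the highest, with 2.48e-07 as the lowest.

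Changes of named genes that turned in direction did not pass the test after turning. In mated minus virgin abdomens under the muscle and tubule scaling these were Mtk (-0.0031), Drs (-0.18), zetaTry (-0.042), gce (-0.20), ry (-0.015), Irk3 (-0.24), Irk2 (-0.22), Pdp1 (-0.28), cwo (-0.33), FASN2 (-0.0095) and Fad2 (-0.12). In P minus M abdomens TotA ranged from -3.43 to 0.00499 (without M2). In mated minus virgin heads Mtk was 0.45 with limma voom and -1.54 to 2.48 (without virgin 3) over omissions. Drs was -0.11 to 1.17, below 0 without virgin 1, virgin 2, M3 or P1, and AttA was -0.12 (without virgin 1) to 1.61. The midgut proteases were above 0 without virgin 1, the highest value of each range over omissions, with kappaTry -4.30 to 2.98, Ser6 -5.08 to 7.32, thetaTry -2.58 to 1.21 and alphaTry -4.58 to 5.50. Ser6 was 0.39 with limma voom and alphaTry 0.96 with the 3 head libraries left out. In P minus M heads that omission gave Jon25Bii 2.57, Jon25Bi 0.62, Jon99Ciii 0.77, Jon99Cii 0.71 and vri -0.015.

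The population numbers did not pair the libraries. Same-numbered libraries correlated above 0.1 in 0 of 9 pairs in abdomens (-0.425 to 0.0336) and 4 of 9 in heads (-0.505 to 0.686), and abdomen and head of a pool in 3 of 9 (-0.404 to 0.26). Libraries correlating best with their own number were 0, 3 and 3. A replicate block gave 4912 calls for mated minus virgin in abdomens, 124 (118 shared with the 241), 39 (M minus virgin) and 75 (P minus virgin) in heads and 4312 for the mating effect between tissues. Under the replicate block Mtk was 0.38 in mated minus virgin heads, and the exact p of the response score was 1 in abdomens and 0.5 in heads, with 0.25 the smallest possible. For P minus M the replicate block called 12 lists in abdomens, adding spermathecal genes (adjusted p = 0.0298), and 7 in heads, losing eggshell (0.0505) and fat body genes (0.0654).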

Other observations

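In mated abdomens the test of embryo transcripts by library was planned on genes not yet examined, but the choice of members with at most 3 virgin counts, the comparison of male transcripts with the muscle list and the look at Osiris genes were made after related results had been seen.

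Genes of hydrocarbon synthesis, odorant binding and the ecdysone response were also among those higher in mated abdomens. All 9 hydrocarbon synthesis genes of the oenocytes rose, also when adjusted over the list alone, with a median log2 change of 0.79 that was -0.12 under the muscle and tubule scaling. FASN2 rose from 161 ± 22.9 to 307 ± 42.0 CPM, Fad2 from 463 ± 97.2 to 799.7 ± 56.9, bond by 1.48 ± 0.21 and eloF by 0.93 ± 0.13; under that scaling FASN2 and Fad2 were at -0.0095 and -0.12, not past the threshold. Camera gave the list an adjusted p of 9.4e-04 (adjusted p = 0.35 with an estimated correlation; fry 0.0013). Of 21 odorant binding protein genes 11 rose and 0 fell, also when adjusted over the list alone, with a median of 0.56 that was -0.33 under the muscle and tubule scaling. Obp56a (FBgn0034468, 2R:19697723-19698508) rose from 4.95 ± 0.799 to 34.4 ± 8.26 CPM, Obp19c from 4.23 ± 2.20 to 77.8 ± 26.04 and Obp56d by 2.09 ± 0.21. Camera gave this list an adjusted p of 0.0017 (adjusted p = 0.34 with an estimated correlation; fry 2.8e-04). Of 21 ecdysone genes 14 rose and 1 fell (14 and 3 adjusted over the list alone), with a median of 0.97. ImpL2, which encodes a secreted antagonist of insulin, rose from 70.9 ± 7.59 to 191 ± 23.3 CPM, and the early response genes Eip74EF, br and Eip75B by 1.65 ± 0.16, 1.04 ± 0.11 and 0.97 ± 0.09. Camera gave the ecdysone list an adjusted p of 6.2e-04 (adjusted p = 0.34 with an estimated correlation; fry 2.1e-04).

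Some blood cell and sex differentiation genes rose as well, while others fell or did not pass. Of 13 blood cell genes 6 rose and 1 fell, also when adjusted over the list alone, with a median of 0.65 that was -0.26 under the muscle and tubule scaling. The GATA factor gene srp rose from 25.9 ± 1.89 to 81.5 ± 9.69 CPM and the peroxidasin gene Pxn by 0.86 ± 0.13; both were named after their values were seen. By camera the adjusted p was 0.015 (adjusted p = 0.44 with an estimated correlation; fry 0.0048), and 0.0791 without virgin 3. Of 10 sex differentiation genes 6 rose and 2 fell, also when adjusted over the list alone, with a median of 0.54 that was -0.40 under the muscle and tubule scaling. Among them fru rose from 3.84 ± 0.719 to 9.65 ± 0.820 CPM and dsx from 9.54 ± 2.05 to 20.02 ± 0.779, genes also named after their values were seen. By camera the adjusted p was 0.046 (adjusted p = 0.34 with an estimated correlation; fry 3.8e-04), which was 0.0773 without virgin 1, 0.0546 without M2 and 0.0895 without P3. Turandot stress genes varied between mated libraries, with summed levels of 359 CPM in M1, 975 in M2, 69.6 in M3, 73.3 in P1, 35.5 in P2 and 572 in P3, against 16.4 to 39.2 in virgins. Of 5 tested members 1 rose, TotM (4.42 ± 1.51, adjusted p = 0.0463 in edgeR), and 0 when adjusted over the list alone; camera did not call the list (adjusted p = 0.12; adjusted p = 0.60 with an estimated correlation; 0.0262 without M3).

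Some mated abdomens held transcripts of genes that the embryo switches on soon after fertilization. Summed over bnk, halo, Z600, SNCF, term, Elba1 and Elba3, which drew attention to the pattern, levels were 12.6 CPM in M2, 13.3 in P1 and 16.5 in P3, 0.218 in M1, 0.0740 in M3 and 0.0561 in P2, and 0 to 0.0419 in virgins. Fertilized eggs held in the abdomen are a candidate explanation, and a further list of early zygotic genes was tested. Its sum did not differ by the exact test (2-sided permutation p = 0.0952) and was lower in mated abdomens, a difference of -9.91 CPM. A sum no higher in mated females had been set beforehand as evidence against the explanation, but slam held 13978 of the 15086 virgin counts of the list (92.7%), so the sum says little of its other members. Of 430 mated counts of the 8 members with at most 3 virgin counts, 90.2% (388) lay in M2, P1 and P3, where 90% had been the bound set for the explanation and these libraries held 50.4% of all mated counts. By library these were 10 counts in M1, 82 in M2, 9 in M3, 204 in P1, 23 in P2 and 102 in P3, against 3 over all virgins. The share lay just above its bound, and the members were chosen after their totals were seen, so retained fertilized eggs stay a hypothesis.

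RNA received from males at mating was considered for the same transcripts. Summed expression of accessory gland genes was 0.395 CPM higher and that of testis genes 1.09 CPM higher in mated than in virgin abdomens (exact 2-sided permutation p = 0.0119 for both, the smallest that 6 libraries against 3 allow), as set beforehand for this explanation. In virgin abdomens 0 of 38 accessory gland and 0 of 30 testis genes reached 1 CPM, and in virgin heads 2 and 3 did. The most abundant members were Acp24A4, at 0.117 CPM in virgin and 0.248 in mated abdomens, Obp56g (0.213 and 0.177), topi (0.797 and 1.57) and Pif1A (0.110 and 0.304), so topi made up most of the testis sum. The list rises of 1.61 and 1.96 times did not exceed the median rise of the muscle list, 2.01 times, so male RNA and a changed share of tissues in the abdomen cannot be told apart as the source of these low levels. By library the male lists did not follow the embryo transcripts, which were high in M2, P1 and P3 alone. The testis list was at 2.32, 2.53 and 2.09 CPM there and at 2.43, 1.97 and 1.95 in M1, M3 and P2. Accessory gland values were 0.986, 1.04 and 1.14 against 0.854, 0.961 and 1.29. Genes of the Osiris family other than Osi19 summed to 97.7 CPM in abdomen P2, against 0.763 to 1.21 in the other mated libraries and 0.105 to 0.359 in virgins (exact 2-sided permutation p = 0.345 for mated minus virgin). In P2, Osi6 was at 39.9 CPM and Osi7 at 32.7.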
